A study of Drosophila melanogaster with 6 samples.

How the data were processed

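The series compared anterodorsal-lineage projection neurons (adPNs), second-order olfactory neurons of the Drosophila brain, between wild-type and acj6 mutant flies at 36 to 40 h after puparium formation. Each genotype had 3 libraries, made from total RNA with a modified SMART-seq2 protocol per the labels, which amplifies full-length cDNA and carries no molecular identifiers. Samples were grouped by the genotype in their labels, and the replicate numbers are those in their titles, which name acj66 for the mutant libraries. The labels do not say whether the libraries came from separate animals or dissections, so p-values measure the spread between these libraries, which may be technical.

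The deposited values are whole-number read counts per gene, 1 file per library, with no normalization. The submitters' processing notes name bcl2fastq 2.19.0.316, STAR 2.5.4 and HTSeq 0.11.2. The genome build, the annotation release and the strand setting of the counting are not given in the sources used here, and no coordinates are printed for that reason. Each file held 17575 entries: 17471 genes with FlyBase identifiers, 96 ERCC spike-in sequences, 3 transgenes and 5 summary entries of the counting program. The spike-ins (15 to 35 counts per library), the transgenes and the summary entries stayed out of library sizes and tests. Reads outside annotated genes came to between 8.59% and 10.9% of the gene counts. Alignments set aside as not unique came to 3.21, 3.74 and 4.16 per gene count in wild-type replicates 1 to 3 and to 2.95, 2.19 and 2.76 in acj6 mutant replicates 1 to 3. Genes with near-identical copies, such as Frq1 and Frq2, lose reads in this way, and their counts are uncertain. Genes that overlap another gene's exons are uncertain too, since the strand setting is not given. Among the genes named here these include Hr3, br, Ten-m, roX1, Frq2, zfh2, Hsp68, VGlut, and the pair ChAT and VAChT. They also include CG7131, the antisense RNA CR43476, CG42331, Myo10A and CG30184, which had large folds, and Hmu, Msp300, hth, pros, Pxn and repo.

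Symbols were taken from the Ensembl gene names by identifier, and 17242 of the 17471 genes matched while 229 did not. Symbols used in the gene lists were brought up to date with the RefSeq gene table. Chromosome arms, transcript lengths (the median over a gene's transcripts) and exon overlaps came from the Ensembl 115 gene models of BDGP6.54, matched by identifier. A length was found for 98.5% of the genes tested.

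The total gene count was 27049408, 34547549 and 24467328 in wild-type replicates 1 to 3 and 38279909, 30980945 and 37469967 in acj6 mutant replicates 1 to 3. With these totals, 3 counts in a library correspond to between 0.0797 and 0.119 CPM. Floors and bounds set at 3 counts, taken over the group, cover counting error only. A gene with no count in a group is given as a bound against that floor, and its fitted log2 fold change is not used as a bound.

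Genes were kept with the filterByExpr rule of edgeR 4.0.16 on the group, which left 9229. The counts were scaled with TMM factors and tested with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, R 4.3.3) on an intercept and genotype over all 6 libraries, two-sided. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05. CPM values are relative to a library's gene counts after TMM scaling, means are given ± SD over 3 libraries, and log2 fold changes (mutant minus wild type) with the standard error from the fit. The adjusted p-values given for genes are from this test.

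The rule for the genes named was fixed before the data were examined, as were the gene lists, the main test and the first set of alternatives. It takes acj6, then the 10 called genes with the highest and the 10 with the lowest log2 fold change whose groups do not overlap and whose higher group averages at least 10 CPM. It adds up to 4 called members with the smallest p from each list, a fixed set (ChAT, VAChT, VGlut, Gad1, C15, Oaz, kn, vvl, Lim1, Piezo, roX1, roX2, repo and Hml), and the most abundant tested member of each marker list. Oaz is given no value, since the tables tie neither its symbol nor its synonyms to an identifier in the files, and it could be among the 229 genes without a match. Further called members of a list are named in a few places and were chosen after their values were seen.

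The 24 lists covered projection neuron and lineage transcription factors, POU and LIM homeodomain factors, cholinergic genes, other transmitter identities, neuropeptides, neurotransmitter receptors, ion channels, the Dpr and DIP, Beat and Side, leucine-rich repeat and other adhesion families, axon and dendrite guidance genes, synaptic vesicle and active zone genes, ecdysone response and stage genes, stress genes, dosage compensation and sex genes, ribosomal proteins, the mitochondrial genome, and markers of glia, hemocytes and fat body, muscle, other brain neurons, progenitors, and epithelium with cuticle and trachea. Each list was tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01 between genes, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. The 5 cell-surface lists were also joined, and their share of called genes was compared with that of other tested genes in a one-sided Fisher's exact test. The difference between the median log2 fold changes of X-linked and autosomal genes was compared over the 10 splits of the 6 libraries into groups of 3, in an exact permutation test whose smallest p is 0.1.

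The alternatives chosen beforehand were DESeq2 size factors, upper-quartile scaling, no filter and a stricter filter on low counts, DESeq2 1.42.0, limma-voom with and without quality weights, robust empirical Bayes, the replicate number as a block, a fold above 2, and each library left out in turn. Removal of each library's transcript-length trend, by an offset from a lowess curve, and thinning of all libraries to the smallest total were added after the data were seen. The test was tried on simulated counts for the 9229 genes with 3 libraries a group. It called 10% of genes changed 1.5-fold, 56% of those changed 2-fold, 78% of those changed 4-fold and 98% of those changed 8-fold, and 5.47% of its calls were unchanged genes. These counts were drawn without a length trend, so the percentages do not cover one. With a length trend as the only difference, steeper than that in the libraries, the test called 1268 simulated genes, and 0 once that trend was removed. The simulated slopes were the same within a group, unlike those of the libraries. Neither number therefore says how many calls a length trend made here, or how well its removal worked.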

Results

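Full-length cDNA libraries of adPNs, whose dendrites target glomeruli of the antennal lobe and relay odour input to higher brain centres, were compared between 3 wild-type libraries and 3 libraries labelled acj6 mutant. acj6 encodes a POU-domain transcription factor expressed in this lineage, and the question set by the series title is how it controls dendrite targeting through genes for cell-surface proteins. Gene counts ranged from 24467328 to 38279909 per library. Across genes, log2 CPM values correlated at 0.923 to 0.934 (Pearson's r) between wild-type libraries, at 0.916 to 0.918 between mutant-labelled libraries, and at 0.896 to 0.910 between the groups. No pair of libraries of a group had counts alike to within sampling noise (chi-square per degree of freedom from 58.2 to 116), which excludes 1 file entered under 2 names but, with amplified reads, says nothing of separate animals or cells. The first principal component, with 30.2% of the variance, separated the 3 wild-type libraries from the 3 mutant-labelled ones.

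acj6 itself (FBgn0000028, X chromosome) was counted at 251 ± 24.2 CPM (SD, n = 3) in the mutant-labelled libraries and at 149 ± 7.96 CPM in the wild type. Its transcript count was therefore higher in the libraries labelled mutant, with a log2 fold change of 0.75 ± 0.12 (SE) and an adjusted p of 0.0124 in edgeR's quasi-likelihood test. The titles of these libraries name acj66, the labels do not give the lesion, and a count over the whole gene does not check the genotype label. Without wild-type replicate 2 the log2 fold change was 0.73 with an adjusted p of 0.0658, and over all alternatives the adjusted p ranged from 5.61e-07 to 0.0658.

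In the mutant-labelled libraries the transcription factor gene kn rose 2.94-fold, the cell-surface genes Dscam2, Dscam3, Dscam4 and Ten-m rose, and the steroid-hormone-response gene Hr3 and the dopamine transporter gene DAT fell. Of 9229 genes tested, 283 were higher and 123 lower, with a median fold of 1.87 among the higher and 0.514 among the lower. All 406 called genes showed no overlap between the groups, against 23.2% of all tested genes and the 10% that chance gives for 3 against 3. The call itself selects for such genes, so this is no separate evidence for them. More than 2-fold changes were called for 123 higher and 60 lower genes. Higher genes were 69.7% of the calls, and 59.3% (208 of 351) once each library's transcript-length trend was removed. Leaving out any 1 of the 6 libraries lowered the count to between 143 (without wild-type replicate 2) and 249 (without wild-type replicate 1), and DESeq2 called 940.

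Transcription factors of projection neurons and of the lineage changed in both directions, and 2 of those that changed, br and Eip93F, are also on the ecdysone list. kn (FBgn0001319), a COE-family factor that specifies neuron identity, went from 454 ± 45.8 to 1333 ± 137 CPM (log2 fold change 1.55 ± 0.12, adjusted p 0.00223). br (FBgn0283451), an ecdysone-induced zinc-finger gene, went from 322 ± 35 to 730 ± 35.2 CPM (1.18 ± 0.11), and Eip93F (FBgn0264490), another ecdysone-induced factor, from 37.3 ± 5.55 to 82.2 ± 13.4 CPM (1.14 ± 0.20). zfh2 (FBgn0004607), a zinc-finger homeodomain gene, fell from 974 ± 158 to 486 ± 71.0 CPM (-1.0 ± 0.15). Together with acj6, these were 4 higher and 1 lower of 27 tested factors, or 6 higher and 2 lower when adjusted over the list alone. C15, a homeobox gene used as an adPN marker, was at 162 ± 30.2 and 159 ± 19.1 CPM, and the 95% interval of its log2 fold change was -0.48 to 0.43. vvl, a lateral-lineage factor (4.73 ± 1.99 and 3.38 ± 1.77 CPM), and Lim1 (8.06 ± 2.55 and 3.63 ± 1.68 CPM) were low in both groups and not called. Among POU and LIM homeodomain genes, acj6 was the 1 called of 12 tested, over all genes and over the list alone.

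The ecdysone response and stage list held 4 higher and 2 lower genes of 27, or 6 and 3 over the list alone. Hr3 (FBgn0000448), a nuclear receptor of the ecdysone cascade, fell from 112 ± 4.2 to 33.2 ± 2.2 CPM (log2 fold change -1.75 ± 0.15, adjusted p 0.00223), and ImpL2, which encodes an insulin-binding protein, fell from 19.0 ± 14.9 to 3.44 ± 0.277 CPM. br and Eip93F rose, as did crol and Cyp18a1, both named after their values were seen. Neither the transcription factor list (camera adjusted p 0.347) nor the ecdysone list (0.335) passed camera's threshold. The median of the transcription factor list was 0.02 and its mean -0.20, while camera gave it an upward direction. Removing the length trend ended the calls of Eip93F, ImpL2, crol and Cyp18a1, limma-voom ended those of ImpL2 and Cyp18a1, and robust variances that of Cyp18a1. The calls of kn, br and Hr3 held in all leave-outs, that of Eip93F only without wild-type replicate 2 or acj6 mutant replicate 1, that of crol only without wild-type replicate 1, and those of ImpL2 and Cyp18a1 in none.

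**Figure D1:**
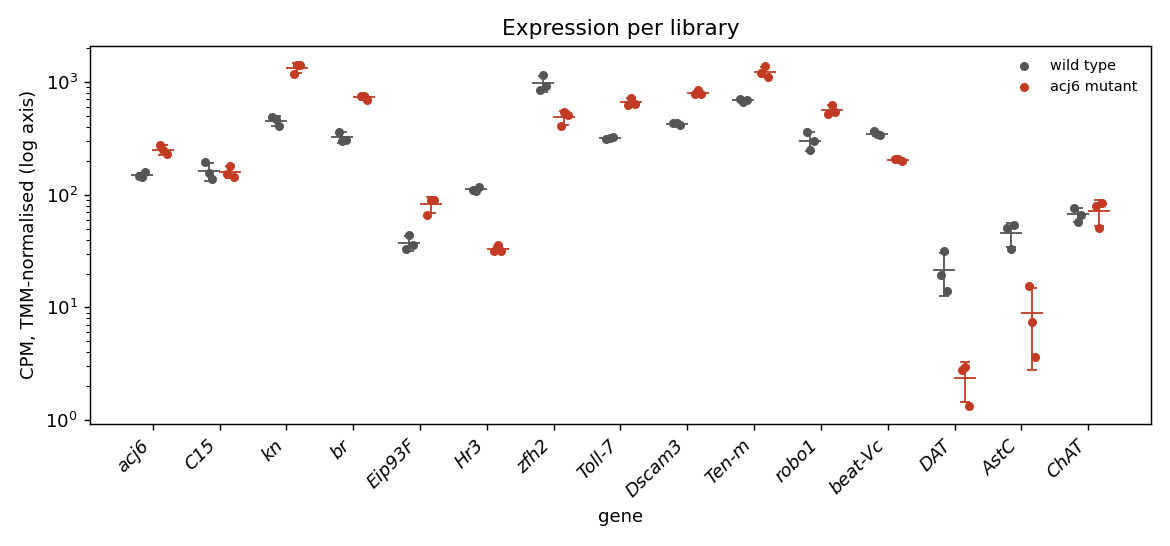
Expression of 15 named genes in CPM after TMM scaling, on a log axis, with 1 point per library, a dash for the mean of 3 libraries and bars for the SD. The acj6 points of the mutant-labelled libraries (mean 251 CPM) lie above those of the wild type (149 CPM), kn rises from 454 to 1333 CPM, Hr3 falls from 112 to 33.2 CPM, and C15 overlaps between groups.

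Genes for cell-surface proteins were called more often than other genes, and most of those called were higher in the mutant-labelled libraries. Of 165 tested genes in the 5 joined lists, 17 rose and 6 fell (22 and 9 over the list alone), which is 13.9% against 4.23% of the other genes (odds ratio 3.67, one-sided Fisher's exact p 8.17e-07). The Dscam genes, immunoglobulin-family receptors, accounted for several: Dscam3 (FBgn0261046) went from 424 ± 7.83 to 799 ± 36.9 CPM (log2 fold change 0.91 ± 0.09, adjusted p 0.00243), and Dscam4 (0.99 ± 0.12) and Dscam2 (0.65 ± 0.09) rose as well. Ten-m (FBgn0004449), a teneurin that matches projection neurons with their sensory partners, went from 691 ± 19.4 to 1227 ± 131 CPM (0.83 ± 0.10). Transcripts of these genes are long, with a median of 4427 bases against 1953.5 for tested genes. In 10000 gene sets matched on length and mean expression the median number called was 18, against 23 in the list (permutation p 0.094). With the length trend removed, 6 surface genes were higher and 8 lower, with an odds ratio of 2.40 (p 0.00407, the highest over all alternatives, whose lowest was 8.88e-10). In that setting 14 surface genes were called, against a median of 12 in matched sets (permutation p 0.33, a test added after the data were seen). An excess over genes alike in length and expression was therefore not shown.

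Called surface genes came from 4 of the 5 families, and differences between families were not tested. Other adhesion and immunoglobulin-family proteins held 10 higher genes and 1 lower of 49 (17 and 1 over the list alone), with a median log2 fold change of 0.33 and a camera adjusted p of 6.32e-05. That list gave an adjusted p = 0.367 with an estimated correlation and 0.131 with the length trend removed, and its lowest over the alternatives was 1.26e-05. It held 3 higher calls and 1 lower with the length trend removed. The 1 that fell was Lac, an immunoglobulin-domain adhesion protein (43.9 ± 11 to 13.2 ± 1.10 CPM), named after its value was seen. Guidance receptors and ligands held 6 higher and 2 lower genes of 43 (9 and 4 over the list alone, camera adjusted p 0.0801). Among them the semaphorins Sema1a (584 ± 69.2 to 962 ± 53.4 CPM, log2 fold change 0.72 ± 0.11) and Sema2b (278 ± 34.1 to 456 ± 39.4 CPM, 0.72 ± 0.12), the semaphorin receptor gene PlexA (0.81 ± 0.12) and the Slit receptor gene robo1 (301 ± 55.7 to 564 ± 56.9 CPM, 0.91 ± 0.15) rose. PlexB (-1.03 ± 0.23) and robo2 (-0.75 ± 0.16) fell, both named after their values were seen. With the length trend removed, the guidance list held 2 higher and 3 lower calls (camera adjusted p 0.987). Leucine-rich repeat proteins had 1 higher and 1 lower gene of 23 (1 and 2 over the list alone, camera adjusted p 0.236). Toll-7 (FBgn0034476), a Toll-family receptor used in olfactory wiring, went from 318 ± 6.15 to 664 ± 51.7 CPM (1.06 ± 0.10, adjusted p 0.00223), and kek2 fell from 139 ± 3.15 to 81.5 ± 6.89 CPM (-0.77 ± 0.13). Beat and Side proteins had 2 lower genes of 21, over all genes and over the list alone (camera adjusted p 0.347). These were beat-Vc (348 ± 14.7 to 205 ± 5.83 CPM, -0.76 ± 0.10) and beat-VII (-0.72 ± 0.15). No Dpr or DIP gene was called by edgeR among 32 tested, over all genes or over the list alone, while 4 had an unadjusted p under 0.05, DESeq2 called 3 and limma-voom 0. The Dpr and DIP list had a camera adjusted p of 0.874, a median of -0.02, a mean of 0.08 and an upward direction in the test. Dscam2, Sema1a and Sema2b lost their calls with the length trend removed, Dscam2 and PlexA without wild-type replicate 2, robo1 without wild-type replicate 3 or acj6 mutant replicate 2, and kek2 without wild-type replicate 2 or 3 or acj6 mutant replicate 3. Sema2b kept its call only without replicate 3 of either group, PlexB only without wild-type replicate 3, and beat-VII and robo2 in no leave-out. The calls of Dscam3, Dscam4, Ten-m, Toll-7 and beat-Vc held in all leave-outs and in all other alternatives except a fold above 2. Of these genes only Toll-7 (2.09-fold) passed that setting, since Dscam3 (1.88), Dscam4 (1.99), Ten-m (1.78) and beat-Vc (0.589) changed by less.

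**Figure D2:**
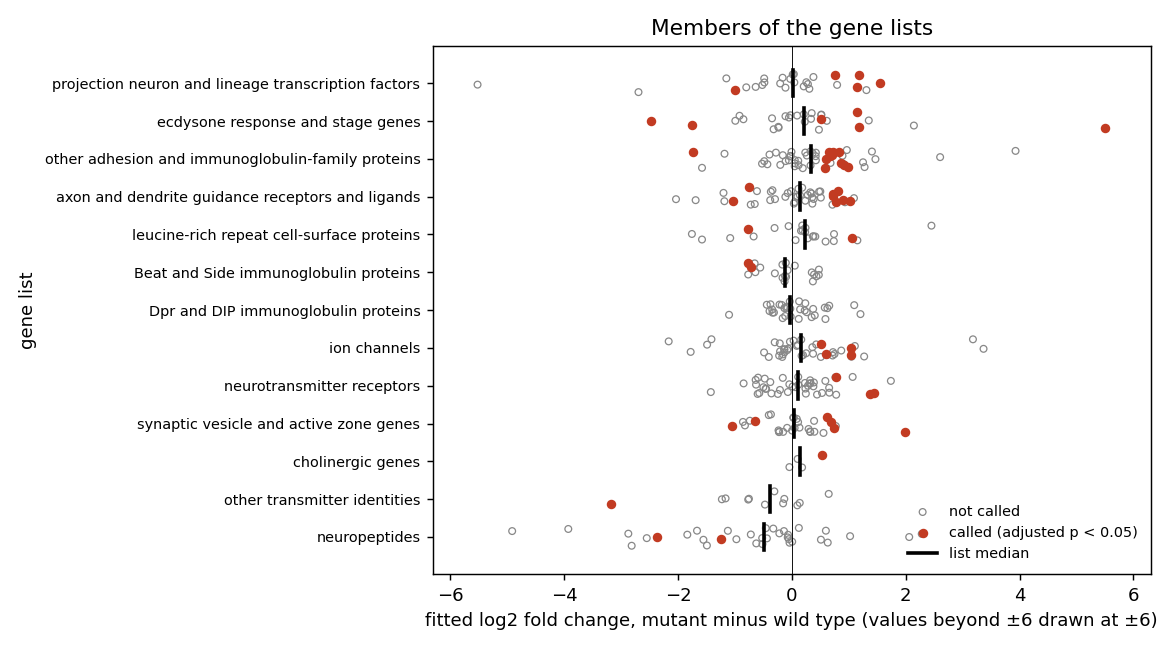
Fitted log2 fold change (mutant minus wild type) of each tested member of 13 gene lists, with filled points for genes called by edgeR at an adjusted p under 0.05, open points for the others and a bar at the list median. Other adhesion and immunoglobulin-family genes have 10 called above 0 and 1 below, and neuropeptides have 2 called below 0.

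Presynaptic genes, ion channels and receptors showed called changes. Their lists did not pass camera's threshold with all libraries and the preset correlation and filter. brp (FBgn0259246), which encodes the active zone scaffold Bruchpilot, went from 3795 ± 157 to 5850 ± 89.8 CPM (log2 fold change 0.62 ± 0.06, adjusted p 0.00243). Over all alternatives the lowest log2 fold change of brp was 0.27 and its highest adjusted p 0.0426. Frq2, a calcium sensor of synaptic terminals, went from 52.9 ± 16.9 to 210 ± 52.0 CPM (1.99 ± 0.26). Rop, a Sec1/Munc18 protein of vesicle fusion, also rose (0.69 ± 0.14), while Syt4, a synaptotagmin, fell (-1.04 ± 0.21). The synaptic list held 4 higher and 2 lower genes of 31 (6 and 6 over the list alone, camera adjusted p 0.817). Of 43 ion channel genes 4 rose and 0 fell (7 and 0 over the list alone, camera adjusted p 0.0766). They were the calcium channel gene cac (0.60 ± 0.12), the NALCN-complex gene unc80 (1.04 ± 0.22) and the potassium channel genes Shal (1.05 ± 0.22) and Shab (0.51 ± 0.12). Removing the length trend ended the calls of cac, unc80 and Shab. With 1 library left out, cac and Rop kept their calls only without acj6 mutant replicate 2, unc80 only without wild-type replicate 3, Shal and Shab only without wild-type replicate 1, and Syt4 only without wild-type replicate 3 or acj6 mutant replicate 1. Shab was lost with upper-quartile scaling too. Piezo, a mechanosensitive channel, was at 41.4 ± 7.69 and 59.0 ± 27.2 CPM and was not called. Among 43 neurotransmitter receptors 3 rose and 0 fell (7 and 6 over the list alone, camera adjusted p 0.347): the octopamine and tyramine receptor gene Oct-TyrR (65.4 ± 11.7 to 169 ± 35.7 CPM), the dopamine receptor gene Dop1R2 (46.2 ± 6.79 to 126 ± 31.8 CPM) and GABA-B-R2 (225 ± 35.3 to 384 ± 37.8 CPM), whose call was lost with the length trend removed and without wild-type replicate 3 or acj6 mutant replicate 1 or 2. With the length trend removed, the receptor list held 2 higher and 3 lower calls.

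Projection neurons of this lineage are cholinergic, and of the genes for acetylcholine, other transmitters and neuropeptides Ace rose and DAT, AstC and Proc fell. Ace, acetylcholinesterase, was the 1 of 4 cholinergic genes called, also over the list alone (1456 ± 19.6 to 2098 ± 114.7 CPM, log2 fold change 0.53 ± 0.08, camera adjusted p of the list 0.184). ChAT (66.8 ± 9.26 and 71.7 ± 18.8 CPM) and VAChT (95.6 ± 5.41 and 92.9 ± 33.6 CPM), the enzyme and the vesicular transporter of acetylcholine, differed by less than the spread between libraries. Among 12 genes of other transmitters DAT, the dopamine transporter gene, fell from 21.5 ± 8.99 to 2.37 ± 0.912 CPM (-3.18 ± 0.48, adjusted p 0.0111) and was the 1 called, with 2 lower over the list alone. VGlut was at 52.6 ± 18.8 and 31.2 ± 0.244 CPM and Gad1 at 10.6 ± 8.52 and 11.6 ± 4.56 CPM, and neither was called. Neuropeptide genes had 0 higher and 2 lower of 34 (1 and 4 over the list alone) and a median log2 fold change of -0.49: AstC fell from 45.5 ± 11.1 to 8.85 ± 6.04 CPM and Proc from 20.6 ± 1.36 to 8.66 ± 1.33 CPM. Camera gave downward shifts of the other-transmitter list (adjusted p 0.0453) and the neuropeptide list (0.0159), and each had an adjusted p = 0.376 with an estimated correlation. The lowest adjusted p over the alternatives was 0.0114 for other transmitters and 0.00347 for neuropeptides. The downward shift was lost for other transmitters without acj6 mutant replicate 3 (adjusted p 0.0594), with upper-quartile scaling and with limma-voom quality weights, and for neuropeptides without acj6 mutant replicate 1 (0.0933) and with fry (0.0686). DAT lost its call without wild-type replicate 2, AstC and Proc with the length trend removed. AstC kept its call only without acj6 mutant replicate 1, and Proc in no leave-out and not with no filter.

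The 79 ribosomal protein genes were shifted upward in camera (median log2 fold change 0.14, adjusted p 1.32e-04). The list had an adjusted p = 0.603 with an estimated correlation and 0.0942 without wild-type replicate 1, did not pass with fry, and its lowest over the alternatives was 2.00e-08. None was called by edgeR, over all genes or over the list alone, 5 had an unadjusted p under 0.05, and DESeq2 and limma-voom each called 0. None of the 12 mitochondrial genome genes was called by edgeR (1 had an unadjusted p under 0.05, DESeq2 and limma-voom each called 0, camera adjusted p 0.295). In all, camera placed 4 of the 24 lists past its threshold, against 7 without acj6 mutant replicate 2, 7 with a stricter filter on low counts, and 0 with an estimated correlation. Splits of the libraries that mixed the genotypes placed between 0 and 4 lists past that threshold. Ion channels passed it with the stricter filter and without wild-type replicate 1 or acj6 mutant replicate 2, and guidance genes with the stricter filter and without acj6 mutant replicate 2.

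The largest fold changes were in genes of low abundance, several of them cuticle genes. Cpr100A and Lcp65Ad, cuticle proteins, averaged 15.4 ± 14.7 and 12.9 ± 14 CPM in the wild type and had no count in any mutant-labelled library. Against a floor of 3 counts over the group they were at least 537-fold and 448-fold lower, or 241-fold and 171-fold without wild-type replicate 2, which held most of their counts. Cpr51A (11.9 ± 11.5 to 0.0382 ± 0.0407 CPM) and Cpr72Eb (17.2 ± 11.4 to 0.286 ± 0.420 CPM), further cuticle proteins, also fell, as did CG1850 (39.8 ± 30.7 to 0.127 ± 0.0914 CPM), CG13722 (10.2 ± 11.7 to 0.0849 ± 0.104 CPM) and CG30184 (21.1 ± 7.15 to 3.96 ± 0.864 CPM). On the higher side CG15080 went from 0.161 ± 0.140 to 11 ± 2.59 CPM, the long noncoding RNA CR44208 from 0.0926 ± 0.160 to 11.1 ± 6.62 CPM, CG42331 from 0.178 ± 0.194 to 19.3 ± 19.4 CPM and Klp59D, a kinesin, from 0.107 ± 0.155 to 10.2 ± 9.72 CPM. Myo10A, vri, CG14257, Sobp, CG7131 and the antisense RNA CR43476 completed the 10 highest, with log2 fold changes from 2.52 to 5.50. The calls of Cpr100A, Lcp65Ad, Cpr51A, Cpr72Eb, CG1850 and CG13722 were lost with limma-voom. Of the highest genes, CR44208, CG42331, Klp59D, Myo10A, vri, CG14257 and Sobp were lost there too, and Myo10A with the length trend removed. Cpr51A also lost its call without wild-type replicate 2, CG15080 without acj6 mutant replicate 2, CG30184 without wild-type replicate 2 or 3, and Sobp without wild-type replicate 2 or 3 or acj6 mutant replicate 3. Calls were kept only without acj6 mutant replicate 2 by vri, CG14257 and Myo10A, only without acj6 mutant replicate 1 by CG42331 and only without wild-type replicate 1 by CG13722. Calls were kept in 2 leave-outs each by Cpr72Eb (without replicate 1 of either group), CR44208 (without wild-type replicate 3 or acj6 mutant replicate 1), Klp59D (without wild-type replicate 2 or acj6 mutant replicate 3) and CR43476 (without wild-type replicate 1 or acj6 mutant replicate 3).

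Lists of markers of other cells held a few called genes, and no marker list passed camera's threshold with all libraries and the preset correlation and filter. Several members, such as Pxn, pros, hth and Msp300, had higher CPM than acj6 and C15 in both groups. A change in such a gene need not mean a change in other cells. Of 18 markers of other brain neurons 4 rose, also over the list alone (camera adjusted p 0.184): Dop1R2, mub (537 ± 82.0 to 863 ± 35.4 CPM), the proneural gene ato (28.0 ± 11.9 to 95.7 ± 33.8 CPM) and the homeobox gene hth (931 ± 25.9 to 1245 ± 111 CPM). Of 16 glial markers nrv2 fell (433 ± 35.4 to 315 ± 7.60 CPM) and was the 1 called, also over the list alone (camera adjusted p 0.0766), and repo, the glial homeobox gene, was at 1.86 ± 1.11 and 1.57 ± 0.906 CPM. Of 14 hemocyte and fat body markers Hmu rose (387 ± 52.1 to 673 ± 67.0 CPM) and was the 1 called, also over the list alone (camera adjusted p 0.0766), while the most abundant, Pxn, was at 4889 ± 257 and 4599 ± 811 CPM. Hml had 1 count over the wild-type libraries and 66 over the mutant-labelled ones and was not called. Of 15 muscle markers Msp300, a nuclear anchorage protein, was called higher (886 ± 51.2 to 1249 ± 73.2 CPM, log2 fold change 0.50), with 4 higher over the list alone (camera adjusted p 0.0849). The Msp300 value turned to -0.12 with the length trend removed. Other brain neurons passed the camera threshold with the stricter filter (adjusted p from 0.0109 to 0.391 over the alternatives). Glial markers passed it without wild-type replicate 3 or acj6 mutant replicate 2 (0.0261 to 0.376), and hemocyte and fat body markers without acj6 mutant replicate 1 and with no filter (0.0246 to 0.376). With 1 library left out, hth kept its call only without acj6 mutant replicate 2, mub only without wild-type replicate 1 or 3, ato only without replicate 2 of either group, Msp300 only without wild-type replicate 1 or acj6 mutant replicate 3, and nrv2 in none. Hmu lost its call without replicate 2 of either group, and hth with upper-quartile scaling and the length trend removed. No progenitor marker was called among 13 tested (2 higher over the list alone, camera adjusted p 0.610), with pros at 2867 ± 160 and 3780 ± 540 CPM, and none of 13 epithelial, cuticle and tracheal markers (1 higher over the list alone, camera adjusted p 0.955), with crb at 4.32 ± 2.38 and 18.8 ± 7.31 CPM. In each of these last lists 2 genes had an unadjusted p under 0.05, DESeq2 called 2 and limma-voom 0. The median was -0.08 and the mean 0.48 for progenitor markers, with an upward test direction. For epithelial markers the median was 0.05 and the mean 0.14, with a downward test direction. The median log2 fold change was 0.82 for hemocyte and fat body markers and 0.63 for muscle markers. It was 0.10 for markers of other brain neurons and -0.31 for glial markers. A difference between the groups in RNA from other cells was not excluded.

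acj6 lies on the X chromosome, so the sex make-up of the groups could differ, and X-linked and dosage compensation genes were examined. Dosage compensation evens X-linked expression between males and females, so the X-autosome difference cannot decide that question. The median log2 fold change of 1560 X-linked genes exceeded that of 7432 autosomal genes by 0.02 (exact permutation p 0.1, the smallest the 10 splits allow). On the X, 50 genes rose and 23 fell (4.68% called), and on the autosomes 224 rose and 93 fell (4.27%). Of 11 dosage compensation and sex genes, roX1, a noncoding RNA of the male dosage compensation complex, went from 1532 ± 131 to 2998 ± 287 CPM (0.97 ± 0.10, adjusted p 0.00243) and was the 1 called, also over the list alone. Its partner RNA roX2 was at 500 ± 64.4 and 484 ± 54.8 CPM. These RNAs did not move together and leave the sex make-up open. The list had a median of -0.05, a mean of -0.54 and a downward direction in camera (adjusted p 0.790).

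**Figure D3:**
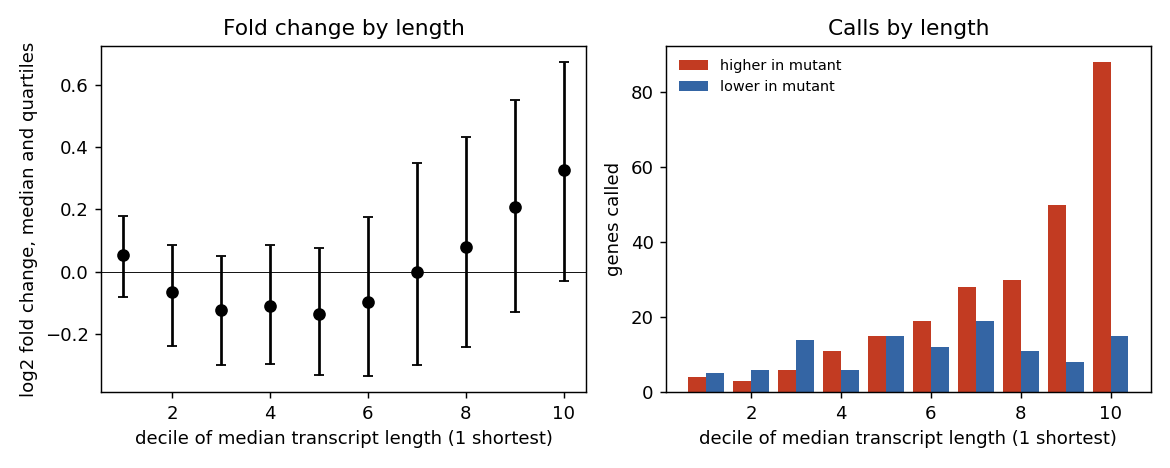
Tested genes with a mean above 8 CPM in 10 groups by median transcript length, shortest first: left, the median log2 fold change (mutant minus wild type) with quartiles; right, the number of genes called higher and lower. In the longest group 88 genes were higher and 15 lower, and in the shortest 4 were higher and 5 lower.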

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

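Removal of the length trend and thinning of the counts were chosen after the data were seen. Of 1421 values of named genes under the alternatives, 1133 kept their direction and side of the threshold, 264 lost the call, 7 gained one and 17 turned direction. The count of called genes was 387 to 480 with other scalings, filters on counts, robust variances and limma-voom, except for 564 with no filter. DESeq2 called 940 (627 higher, 313 lower), among them all 406, and a fold above 2 left 183 (123 higher, 60 lower). The cause of the DESeq2 difference was not tested. With 1 library left out, which leaves fewer samples, 143 to 249 genes were called (109 to 188 higher, 34 to 64 lower), and the acj6 log2 fold change was 0.68 to 0.83. Same-numbered libraries of the groups did not deviate together (correlations 0.02, -0.00 and 0.05), so the numbers were not taken as pairs, and not every library correlated best with its own number. With the replicate number as a block 293 genes were called (215 higher, 78 lower), and of 70 named genes called without it 50 were called. Removal of the length trend turned Msp300 to -0.12, pros to -0.049 and C15 to 0.082. With 1 library left out, log2 fold changes of genes not called went from -0.14 to 0.14 for C15, from -0.74 to 0.30 for repo, from -0.32 to 0.93 for Gad1, from -0.133 to 0.060 for roX2, from -0.23 to 0.019 for Pxn, from -0.36 to 0.18 for VAChT and from -0.032 to 0.30 for ChAT. Lists past the camera threshold numbered 7 with the stricter filter, 0 with an estimated correlation, 2 with fry and 3 to 7 with 1 library left out, and the cause was not tested. The odds ratio of the surface genes stayed between 2.40 and 5.01, with Fisher's exact p at most 0.00407, and the X-autosome difference between 0.00 and 0.04. That Fisher's exact test does not match genes on length or expression. Thinning to the smallest total gave 407 calls.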

Other observations

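Of the tests below, those of the length trend, lineage share and whole-group exchange for acj6, of length removal, depth and scaling for the calls, of matched sets with the length trend removed, and of the cuticle genes were chosen after the results were seen. Stress genes changed in both directions in the mutant-labelled libraries. Of 34 tested, 2 rose and 2 fell (4 and 2 over the list alone, camera adjusted p 0.184). CG14186 went from 160 ± 16.5 to 339 ± 8.76 CPM (log2 fold change 1.08 ± 0.12) and Hsp68, an inducible chaperone, from 69.4 ± 5.58 to 110 ± 8.42 CPM (0.66 ± 0.15). Xbp1, a factor of the unfolded protein response, fell from 464 ± 59.6 to 255 ± 15.1 CPM (-0.86 ± 0.12), and the small heat shock gene Hsp26 from 3946 ± 514 to 2530 ± 109 CPM (-0.64 ± 0.10). The call of Hsp68 was lost in all 6 leave-outs.

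Cuticle protein genes, a family chosen after 4 members appeared among the lowest folds, divided between the groups. Of 125 in the files 30 were tested, of which 6 fell (Cpr100A, Lcp65Ad, Cpr51A, Cpr72Eb, Edg78E and Cpr97Eb) and Cpr73D rose (6.15 ± 2.28 to 30.9 ± 12.6 CPM). The summed family stood at 113 ± 54.8 CPM in the wild type and 88.8 ± 8.61 CPM in the mutant-labelled libraries (exact permutation p 0.8, smallest possible 0.1). Edg78E and Cpr97Eb kept their calls in no leave-out and not with limma-voom, Cpr97Eb also not with no filter, robust variances, length removal or thinning, and Cpr73D kept its call only without wild-type replicate 2 or acj6 mutant replicate 1.

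The first pattern is the higher acj6 count in the mutant-labelled libraries. A length trend between libraries is argued against by the acj6 log2 fold change of 0.77 after that trend was removed. A larger share of lineage cells, as the whole cause, is argued against by the upper 95% bound of the log2 fold change of C15, 0.43, below the fitted 0.75 of acj6. The mCD8-GFP transgene was higher by 0.27 in mean log2 CPM, so a partial contribution of cell share is not excluded. An exchange of 1 library pair is argued against because the splits that exchange 1 pair called 0 genes with edgeR, with 252 to 395 at an unadjusted p under 0.05. An exchange of all labels of both groups would change the sign of the 1.69-fold difference and cannot be told apart from the labelled grouping, since no mark of the allele is in the counts. An allele that may leave, or raise, a transcript stays open as the biological explanation and was not tested.

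The second pattern is that higher calls outnumber lower ones and fall in long transcripts (median 3879 bases for higher calls, 2162.5 for lower). Deeper mutant libraries are argued against by thinning, after which 70.0% of calls were higher, and scaling by the 65.4% that were higher with upper-quartile factors. A length effect stays open: 59.3% of calls were higher once each library's length trend was removed, and of the 122 calls lost, whose median log2 fold change went from 0.76 to 0.52 with a median SE of 0.16 before and 0.15 after, 104 were higher, while per-library slopes also spread within the wild type (-0.13 to 0.04, exact permutation p of the group difference 0.3). Per gene count, alignments set aside as not unique were higher in every wild-type library than in any mutant-labelled one. Wild-type replicates 2 and 3 had the highest ratios and the lowest slopes, and acj6 mutant replicate 2 the lowest ratio and the highest slope. The orders differed elsewhere, since wild-type replicate 1 had a higher slope than acj6 mutant replicates 1 and 3. Whether this difference between the libraries made calls was not tested. A length effect may also account for the excess of called surface genes over other genes, given the permutation p of 0.094 against sets matched on length and expression (0.33 with the trend removed), and an effect of acj6 on long neuronal genes was not tested.

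The third pattern is the loss of 6 cuticle genes. A shared source of cuticle RNA in the wild-type libraries, such as epidermal cells, stays open: all 6 were highest in wild-type replicate 2, which shared regulation could give as well, and 1 cuticle gene, Cpr73D, rose. The sum of the cuticle genes other than the 6 was 47.6 to 55.7 CPM in wild-type and 78.7 to 96.2 CPM in mutant-labelled libraries, against more epidermal RNA in the wild type, but a sum that leaves out the genes that fell excludes nothing. The fixed epithelial markers did not pass the threshold as a list (camera adjusted p 0.955). A different developmental time of the groups stays open with 6 called ecdysone and stage genes, which a genotype effect could give as well.

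Of the 10 splits of the 6 libraries into groups of 3, 1 split, the labelled one, called as many as 406 genes, and the highest other called 0 (edgeR, 1533 against 252 to 395 at an unadjusted p under 0.05). For the lists, 3 of the 10 splits gave 4 or more past the threshold, with 4 in the labelled split and 4 in the highest other. The splits other than the labelled one, where edgeR called 0 genes, placed between 0 and 4 lists past it. Passing camera at the preset correlation is therefore not by itself evidence of a genotype difference. For the surface genes 1 of 10, the labelled split, gave an odds ratio (3.67), and none could be computed in the others, where no gene was called, so the splits say nothing about that list. With 10 splits the share cannot fall under 0.05.

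The mCD8-GFP transgene, a membrane marker, was at 3595 ± 570 CPM in the wild type and 4304 ± 233 CPM in the mutant-labelled libraries. Among called genes 5 had no symbol, and the tables do not say whether Oaz, which was not matched, is 1 of them; of these FBgn0261613 rose with a log2 fold change of 1.43 and FBgn0259234 with 1.66.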
